A study of Bos taurus with 12 samples.

How the data were processed

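Total RNA from cultured bovine chromaffin cells was labelled with biotin and hybridised to single-colour Affymetrix bovine arrays, per the labels' protocols. The deposited table held log2 expression values of 24128 probe sets on 12 arrays, which the authors made with RMA, per the submitters' processing notes. RMA corrects background, normalises arrays to each other and summarises the probes of a set, which compresses small differences of dim transcripts. Its version and settings are not given in the sources used here. The log2 unit follows from the range of the deposited values, 2.88 to 14.14. No values were rescaled before testing.

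Groups, doses and times were taken from the sample labels: untreated, IL6 (10 nM, 24 h), IFNα (1 nM, 24 h) and histamine (10 µM, 6 h), with 3 arrays each. The design text calls the triplicates technical repeats, so the spread between arrays is not read as that between separate cultures or animals. Of the probe sets, 112 control probe sets were left out and 24016 were tested. Gene names came from the platform annotation supplied with the values, updated through a table of cattle genes. It gave 1 symbol for 13292 probe sets, several for 86 and none for 10638. Of the first, 13263 were matched by gene identifier and 2 by accession, 27 kept the platform's symbol, and 1 symbol was updated. Probe sets with several symbols or none were tested but not named. A gene with several probe sets was represented by the one with the highest mean over all arrays, and the mean of all its probe sets was an alternative. Among named genes with several probe sets, another probe set was called in the opposite direction for 0 of 23 after IL6, 0 of 18 after IFNα and 1 of 19 after histamine. IL6ST, which the rule for named genes lists, had no named probe set here.

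Comparisons used limma 3.58.1 in R 4.3.3: lmFit with a mean per group over all 12 arrays, then eBayes with a mean-variance trend, and Benjamini-Hochberg adjustment over the probe sets tested. A probe set was called at an adjusted p under 0.05 and a fold of at least 1.5. Each treatment was compared with untreated cells, IL6 was compared with IFNα, and a moderated F test covered the 4 groups. Standard errors come from this fit, and SDs are over the 3 arrays of a group. Gene lists were tested with camera at a preset correlation of 0.01 between genes, with adjustment over the 22 lists of a comparison. Camera with an estimated correlation and fry were alternatives. Fry tests whether a list's genes move, on balance, in a single direction and compares them with no other genes. Overlaps of calls were set beside the overlap of independent lists. Fold changes were set beside 50 draws of all 12 arrays, controls included, simulated without any change. Noise in these draws was independent between probe sets, and the comparisons in a draw shared its controls.

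The tests, the 22 gene lists and the rule for named genes were fixed before the data were examined. Named were the 10 genes with the largest rise and the 10 with the largest fall among called genes whose treated arrays lay on the same side of all untreated arrays, up to 4 called members of each list, a fixed set of genes of the chromaffin cell and of cytokine signalling, the 5 largest differences each way between the cytokines, and the 5 shared genes with the largest smaller change. Genes outside this rule are marked in the text as chosen after their values were seen, except the genes called in opposite directions by the cytokines, all of which are named. Data were simulated for IL6 against untreated with the real means and spread (24016 probe sets). The procedure recovered 42% of changes of 1.5-fold, 98% of 2-fold and 100% of 4-fold, with 2 false calls. A change of 1.5-fold sits at the fold minimum itself, and 90% of these passed the adjusted p alone. Noise shared between probe sets was not simulated, so the false calls may be too few for these data.

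Alternatives fixed beforehand were other fold minimums, limma's treat at 1.2-fold, eBayes without a trend or robust, array weights, leaving out the dimmer 50% of probe sets, median centring, cyclic loess and quantile normalization on top of the deposited values, a fit of the compared groups alone, the repeat number as a block, separation of arrays without a test, the mean of all probe sets of a gene, and leaving out each array in turn. Leaving out 3 arrays with raised hypoxia genes was added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.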

Results

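Transcript levels were measured in cultured bovine chromaffin cells, the catecholamine-secreting cells of the adrenal medulla, on 12 single-colour Affymetrix expression arrays. Cells were left untreated, or were treated with interleukin-6 (IL6) at 10 nM for 24 h, with human interferon alpha (IFNα) at 1 nM for 24 h, or with histamine at 10 µM for 6 h. Each of the 4 groups had 3 arrays. The submitters describe these triplicates as technical, so every p-value here measures only the spread between these arrays. The time for which the untreated cells were kept is not given in the sources used here. The mean of each array was 6.79 on the log2 scale. Correlations between arrays of the same group ran from 0.993 to 0.998 across probe sets, and no pair of repeats shared more than 4.04% of its values exactly. The values carry no detection calls, and the number of arrays limits the precision. Where the lower mean of a gene lay below the lower quartile of every array (5.02 to 5.11), its fold is read as a lower bound, in each comparison below. Among named genes this held for PTHLH, CUX2, SOCS3, VIP and EGLN3 after IL6, for IFI44, MX2, GBP4, S100A12, CCL8, IL6 and STAR after IFNα, for TAC1, VIP, ZMYND12, CXCL14, SELP and CLDN5 after histamine, and for KCNJ8 and IFI44 between the cytokines. PENK, TH and CHGA in untreated cells (13.89, 13.45 and 13.62), ISG15 after IFNα (13.73) and SCG2 after histamine (13.87) lay close to the highest values on the arrays (14.01 to 14.14), so a small change there does not show stability and the folds of ISG15 and SCG2 are also read as lower bounds. Of 24016 probe sets tested, 11783 (49.1%) differed among the 4 groups in limma's moderated F test.

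The first comparison asked how IL6 changes the transcripts of chromaffin cells. IL6 raised the neuropeptide transcript GAL, which encodes galanin, by 2.73-fold, from 11.66 ± 0.03 to 13.11 ± 0.02 on the log2 scale (SD, n = 3 each). Among called genes with a symbol, KCNJ8, a pore subunit of ATP-sensitive potassium channels, rose most (6.85-fold, log2 change 2.78, SE 0.11). It was followed by the chemokine CXCL13 (6.13-fold, SE 0.18), PTHLH, which encodes parathyroid hormone-related protein (at least 5.16-fold, SE 0.13), and the transcription factor MYB (4.69-fold, SE 0.09). GAP43, a protein of growing axons, rose 4.37-fold, and SOCS3, the feedback inhibitor of IL6 receptor signalling, rose at least 2.43-fold (log2 change 1.28, SE 0.07). The largest fall among them was that of TM4SF4, a membrane protein of the transmembrane 4 family, with a log2 change of -1.90 (SE 0.09). The melanocortin receptor MC4R fell by 1.30 and FGF13 fell by 1.32 on the log2 scale. GRIA3, ANGPT2, KCNE1 and TNFAIP6 were also among the 10 largest rises, with log2 changes of 2.12, 2.05, 1.96 and 1.88. CUX2, SEPTIN4, LOC511175, RPRM, OMG and ADGRL4 were among the 10 largest falls, with log2 changes between -1.24 and -1.04.

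Among IL6-family and STAT3 target genes, 6 of 20 measured members rose after IL6, none fell and 14 were not called. CEBPD rose 3.60-fold, OSMR, a receptor subunit of the IL6 family, rose 1.91-fold, and JUNB rose 1.66-fold. This list was called by camera (adjusted p = 2.95e-06) and remained called with an estimated correlation (adjusted p = 0.00938). STAT3 itself had a log2 change of 0.35 (limma, adjusted p = 0.000141), below the fold minimum. Of the neuropeptides and peptide hormones, 4 of 22 rose and 1 fell. Besides GAL and PTHLH, NPPA rose 2.08-fold and VIP rose at least 1.74-fold, while NXPH1, chosen after its values were seen, fell by 0.79 on the log2 scale. The camera call of this list (adjusted p = 0.00218) was lost with an estimated correlation (adjusted p = 0.094). Among immediate early and calcium- or cAMP-responsive genes, 5 of 30 rose and 1 fell. CREM rose 2.51-fold, ATF3 2.10-fold and JUNB as above, JUN and KLF10, chosen after their values were seen, rose 1.55-fold each, and NR4A2 fell by 0.85 on the log2 scale. NR4A2 is represented by the brightest of its 4 probe sets, and the others ranged from -0.09 to 0.06. The call of this list had an adjusted p = 0.000435, against adjusted p = 0.094 with an estimated correlation. FOS and NR4A1 were not called after IL6, with log2 changes of 0.50 and 0.18. FOS passed the call without IL6 repeat 1, with a log2 change of 0.67, and NR4A1 had -0.36 without the 3 arrays with raised hypoxia genes.

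A few catecholamine genes moved after IL6: 2 of 16 rose, 2 fell and 12 were not called. The sulfotransferase SULT1A1 rose 2.41-fold and the vesicular monoamine transporter SLC18A2 rose 1.81-fold, from 11.50 ± 0.06 to 12.35 ± 0.25 (SD, n = 3). MAOB, a monoamine oxidase, fell by 0.82 on the log2 scale. PNMT, the enzyme that makes adrenaline from noradrenaline, fell by 0.71 (SE 0.23; limma, adjusted p = 0.0451), and this call was lost when any of 7 of the 12 arrays was left out (adjusted p 0.0547 to 0.136). The tyrosine hydroxylase gene TH had a log2 change of 0.21, and DBH had -0.59 (limma, adjusted p = 0.0914). DBH passed the call when IL6 repeat 3 was left out, with a log2 change of -0.84. Leaving out the 3 arrays with raised hypoxia genes (IL6 repeats 2 and 3, IFNα repeat 3) keeps IL6 repeat 1 alone. The log2 changes were then -1.13 for DBH and -1.18 for PNMT, and 0.62 for SLC18A2 in place of 0.85. On IL6 repeats 1, 2 and 3, DBH read 10.17, 10.76 and 11.22 and PNMT read 6.94, 7.49 and 7.79. SLC18A2 read 12.12, 12.32 and 12.61 there, and 11.36, 11.37 and 12.27 on IFNα repeats 1, 2 and 3. PENK, which encodes proenkephalin, and CHGA, which encodes chromogranin A, had log2 changes of -0.06 and -0.15. SLC18A2 was the single called member of 16 secretory granule and peptide processing genes, and 0 of 30 exocytosis and calcium channel genes were called by limma at a fold of 1.5, while 13 had an unadjusted p under 0.05. Camera called neither these 2 lists (adjusted p 0.117 and 0.413) nor the catecholamine list (adjusted p = 0.557; median 0.03, mean -0.02). Among 33 receptor genes, NTRK2, the receptor of brain-derived neurotrophic factor, rose 2.87-fold and the prostaglandin receptor PTGER3 rose 1.61-fold, whereas HRH1 and IFNAR1 had log2 changes of -0.20 and 0.16 and were not called (camera for the list, adjusted p = 0.451).

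**Figure D1:**
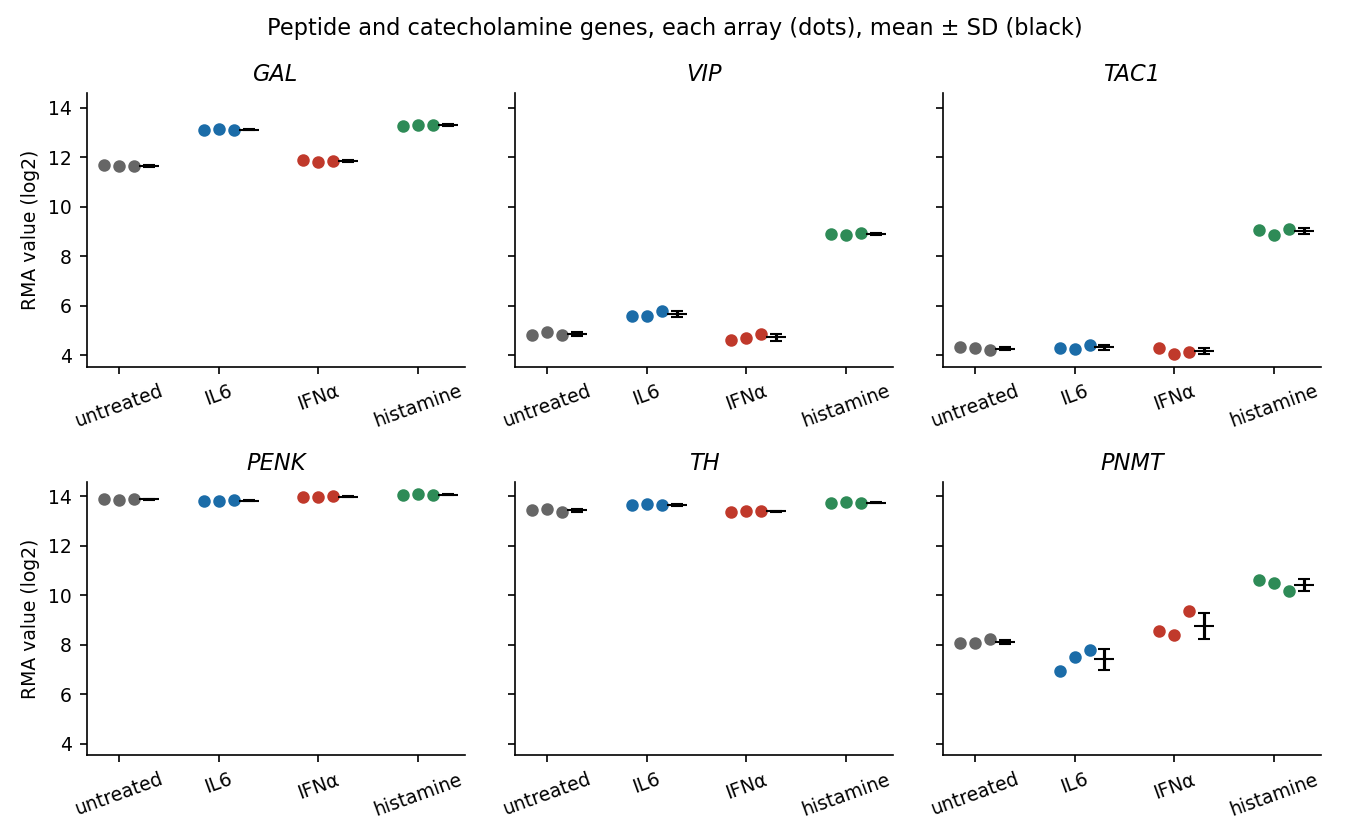
RMA values on the log2 scale (y axis) of 6 genes on each array, by treatment group (x axis), with dots for single arrays and black marks for the mean and SD of 3 arrays. GAL lay near 11.66 in untreated cells, 13.11 after IL6 and 13.31 after histamine, while TAC1 and VIP reached 9.02 and 8.90 after histamine, and PENK and TH, close to the highest values on the arrays (14.01 to 14.14), had log2 changes of at most 0.30.

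Of 38 interferon-response genes, 3 rose after IL6, none fell, and the camera call (adjusted p = 0.00108) was lost with an estimated correlation (adjusted p = 0.267). The 3 were IFI27 (2.24-fold), NMI (2.23-fold) and IFITM1 (1.52-fold), of which IFITM1 had a log2 change of 0.57, below the fold minimum, without IL6 repeat 3. MX1 and ISG15 had log2 changes of 0.20 and 0.25 and were not called. ISG15 passed the call when untreated repeat 1 was left out, with a log2 change of 0.60. Among 16 MHC class I presentation genes, TAP1, a peptide transporter, rose 1.62-fold (camera, adjusted p = 0.00666; adjusted p = 0.267 with an estimated correlation). Of 22 acute phase genes, the complement genes C3 and C1S rose 1.62-fold and 1.60-fold (camera, adjusted p = 0.00218; adjusted p = 0.094 with an estimated correlation), and the C3 call was lost without untreated repeat 2, IL6 repeat 2 or IL6 repeat 3 (log2 change 0.53 to 0.69). None of the 35 cytokine and chemokine genes listed, which do not include CXCL13, rose and 2 fell, CXCL12 by 0.90 and IL18 by 0.67 on the log2 scale, although the list as a whole was shifted upward (median 0.15, with 3 higher and 2 lower without the 3 arrays with raised hypoxia genes; camera, adjusted p = 0.00957; adjusted p = 0.267 with an estimated correlation). Of 22 genes of the matrix protease and plasminogen system, PLAU, TIMP1 and PLAT rose, by 1.84-fold, 1.64-fold and 1.56-fold (camera, adjusted p = 0.451). PLAT had a log2 change of 0.57, below the fold minimum, without IL6 repeat 1. No cell cycle gene of 28 was called by limma at a fold of 1.5, while 14 had an unadjusted p under 0.05, and this list lay lower (median -0.14; camera, adjusted p = 0.00745; adjusted p = 0.267 with an estimated correlation).

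Glycolysis and hypoxia-response genes rose after IL6 on part of the arrays. Of 28 measured members 7 rose and none fell, or 11 and none adjusted over the list alone, with a list median of 0.49 (camera, adjusted p = 0.000122; adjusted p = 0.464 with an estimated correlation). NDRG1 had a log2 change of 1.61 (SE 0.48), EGLN3 of 1.51 (SE 0.24) and LDHA, the lactate dehydrogenase A gene, of 1.35 (SE 0.36). The mean of the list relative to untreated was 0.07, 0.60 and 0.92 on IL6 repeats 1, 2 and 3, and -0.05, -0.03 and 0.64 on IFNα repeats 1, 2 and 3. The calls of NDRG1 and LDHA were lost when any of 5 of the 12 arrays was left out (adjusted p up to 0.141 and 0.0867), namely each untreated array and IL6 repeats 2 and 3. Without IL6 repeats 2 and 3 and IFNα repeat 3 the log2 changes were 0.54, 1.00 and 0.61 for NDRG1, EGLN3 and LDHA, and PFKFB3 (log2 change 1.01) lost its call with 0.34. Markers of adrenal cortical cells were lower after IL6: CYP11A1, the first enzyme of steroid synthesis, fell by 1.27, STAR by 0.85 and HSD3B1 by 0.78 on the log2 scale. These were 3 of 17 cortex markers, and none rose (camera, adjusted p = 0.0022; adjusted p = 0.0713 with an estimated correlation). Other cell type markers went both ways: of 18 leukocyte markers CORO1A and CD14 rose 3.25-fold and 2.05-fold and ITGB2 fell by 0.95, and of 17 fibroblast markers POSTN rose 1.92-fold and ACTA2 fell by 0.67 on the log2 scale (camera, adjusted p 0.117 and 0.621; fibroblast median 0.05, mean -0.06). Among 16 endothelial markers EMCN fell by 0.60, or by 0.56, below the fold minimum, without untreated repeat 3 (camera for the list, adjusted p = 0.223). GAP43 was the called member of 9 Schwann cell markers, and limma called no erythrocyte marker of 7, of which 2 had an unadjusted p under 0.05.

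In all, limma called 573 probe sets after IL6, 345 higher and 228 lower, at an adjusted p under 0.05 and a fold of at least 1.5. They represented 158 genes that rose and 95 that fell, and 250 carried no single gene symbol. In each of the 573 the 3 IL6 arrays lay on the same side of all 3 untreated arrays, as did 33.9% of all probe sets, against 10% by chance. Without the 3 arrays with raised hypoxia genes (IL6 repeats 2 and 3, IFNα repeat 3), an alternative chosen after seeing the data in which the lone IL6 array is assumed to vary like the other groups, 695 probe sets were called, 459 of them shared, and none changed sign. In that setting the hypoxia, neuropeptide, MHC class I, cytokine and cell cycle lists lost their camera calls (adjusted p 0.275, 0.0923, 0.0923, 0.163 and 0.0923). Their medians there were 0.06, 0.14, 0.07, 0.10 and -0.12, against 0.49, 0.14, 0.06, 0.15 and -0.14 with all arrays. OSMR, JUNB, C3, IFITM1, NDRG1 and INSIG1 were no longer called, with log2 changes of 0.49, 0.35, 0.33, 0.49, 0.54 and -0.28. With the mean of all probe sets of a gene, C3, CREM, EMCN, IFITM1, LDHA, NR4A2 and PFKFB3 were not called, with log2 changes of 0.27, 0.41, -0.57, 0.37, 0.42, -0.23 and 0.36. Adjusted over the list alone, the counts also differed for neuropeptides (5 rose, 1 fell) and catecholamine genes (2 rose, 3 fell), and were the same as above for the other lists with called members.

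IFNα, the ligand of the type I interferon receptor, raised nearly the whole set of interferon-response genes in the same cells. RSAD2, which encodes the antiviral protein viperin, rose 121-fold, from 5.56 ± 1.39 to 12.47 ± 0.07 on the log2 scale (SD, n = 3 each). Its 3 untreated arrays read 7.16, 4.79 and 4.72, and without untreated repeat 1 its log2 change was 7.71 in place of 6.91, a lower bound for the same reason as above. IFI44 rose at least 77.7-fold (SE 0.08 on the log2 scale), IFI44L 68.6-fold (SE 0.09), the ubiquitin-like modifier ISG15 at least 49.9-fold (SE 0.21) and IFI27 48.4-fold (SE 0.07). Of 38 measured interferon-response genes 37 rose and none fell, with a median log2 change of 2.95 (camera, adjusted p = 6.98e-69; adjusted p = 0.000278 with an estimated correlation). The exception was HERC5, chosen after its values were seen, with a log2 change of -0.46 that missed the fold minimum. MX1, MX2, XAF1, GBP4 and LOC100298356 were the other genes among the 10 largest rises, with log2 changes between 4.40 and 5.78.

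The machinery of MHC class I antigen presentation rose with it: 13 of 16 members rose after IFNα and none fell (camera, adjusted p = 1.71e-23; adjusted p = 0.00531 with an estimated correlation). The peptide transporter TAP1 rose 11.5-fold, the immunoproteasome subunits PSMB9 and PSMB8 rose 10.4-fold and 6.81-fold, and the class I heavy chain gene BOLA rose 3.32-fold. Among acute phase genes, the complement components C1R and C1S rose 4.35-fold and 2.99-fold and SERPING1, their inhibitor, rose 2.19-fold, while A2M fell by 1.00 on the log2 scale; camera did not call these 22 genes (adjusted p = 0.539). Of 35 cytokine and chemokine genes 5 rose and 2 fell (camera, adjusted p = 0.0885). The risers were CSF1 (2.00-fold), CCL8 (at least 1.92-fold), IL6 itself (at least 1.88-fold), CCL5 (1.85-fold) and IL7, and IL18 and TGFB2 fell; IL7, IL18 and TGFB2 were chosen after their values were seen. The other CSF1 probe set had a log2 change of 0.22 and was not called. The IL6 transcript was dim, at 4.45 ± 0.10 in untreated and 5.36 ± 0.37 in treated cells (SD, n = 3).

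The largest falls after IFNα among called genes with a symbol were those of CNTN1 and TNFAIP6. CNTN1, a neuronal adhesion protein, had a log2 change of -2.15 (SE 0.14), and TNFAIP6, a hyaluronan-binding protein, had -2.08 (SE 0.09). CIBAR1 fell by 1.65, FITM2 by 1.62, MTURN by 1.49, the proto-oncogene MYC by 1.46, and S100A12 by 1.45 on the log2 scale. SULT1E1 fell by 1.25. GAP43 and NTRK2, both higher after IL6, fell by 1.34 and 1.32 after IFNα. Cortex markers were lower here too: 5 of 17 fell and none rose, among them CYP21A2 by 1.22, STAR by 1.08 and CYP11A1 by 1.06 on the log2 scale (camera, adjusted p = 1.35e-05; adjusted p = 0.00648 with an estimated correlation). EMCN and ACTA2, markers of endothelial and mural cells, fell by 0.89 and 0.76 (camera for the lists, adjusted p 0.0505 and 0.0536).

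Genes that define the chromaffin cell were not called after IFNα: 0 of 22 neuropeptides, 0 of 16 catecholamine genes, 0 of 16 granule genes and 0 of 30 exocytosis genes (camera, adjusted p at least 0.584). In these lists limma gave an unadjusted p under 0.05 for 9, 7, 4 and 10 genes, and fry adjusted p of 0.571, 0.694, 0.0433 and 0.00428. GAL, PENK, TH and CHGA had log2 changes of 0.19, 0.10, -0.05 and 0.02, and STAT3, SOCS3, JUNB, FOS and NR4A1 of 0.09, -0.10, 0.24, 0.38 and 0.26. PNMT had a log2 change of 0.65 (SE 0.23; limma, adjusted p = 0.0689), was called when adjusted over the list alone, and passed the call when IL6 repeat 1, IL6 repeat 3 or IFNα repeat 2 was left out (log2 change 0.65 to 0.85). Its 3 IFNα arrays read 8.55, 8.38 and 9.38, and without the 3 arrays with raised hypoxia genes, the last of these among them, its log2 change was 0.34 and was not called. VIP, DBH, HRH1 and IFNAR1 were not called, with log2 changes of -0.13, -0.22, -0.15 and -0.18. In the IL6-family and STAT3 list OSMR rose 1.87-fold and MYC fell, and 18 of 20 members were not called (camera, adjusted p = 0.371). Among immediate early genes MYC, ATF3 and SGK1 fell and none of 30 rose (camera, adjusted p = 0.655); the SGK1 call was lost without untreated repeat 1, untreated repeat 3 or IFNα repeat 3 (log2 change -0.64 to -0.44), and with the mean of its probe sets (-0.44). Apart from PNMT, counts adjusted over the list alone were the same.

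Limma called 807 probe sets after IFNα, 524 higher and 283 lower, which represented 262 genes that rose and 100 that fell. The 3 treated arrays lay on the same side of all 3 untreated arrays in 806 of them, as in 32.9% of all probe sets, against 10% by chance. No hypoxia gene of 28 was called by limma at a fold of 1.5, while 7 had an unadjusted p under 0.05 (camera, adjusted p = 0.391), although the list mean stood at 0.64 on repeat 3. Among 33 receptors NTRK2 was the called member (camera, adjusted p = 0.761). Without the 3 arrays with raised hypoxia genes, 777 probe sets were called and 727 were shared.

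**Figure D2:**
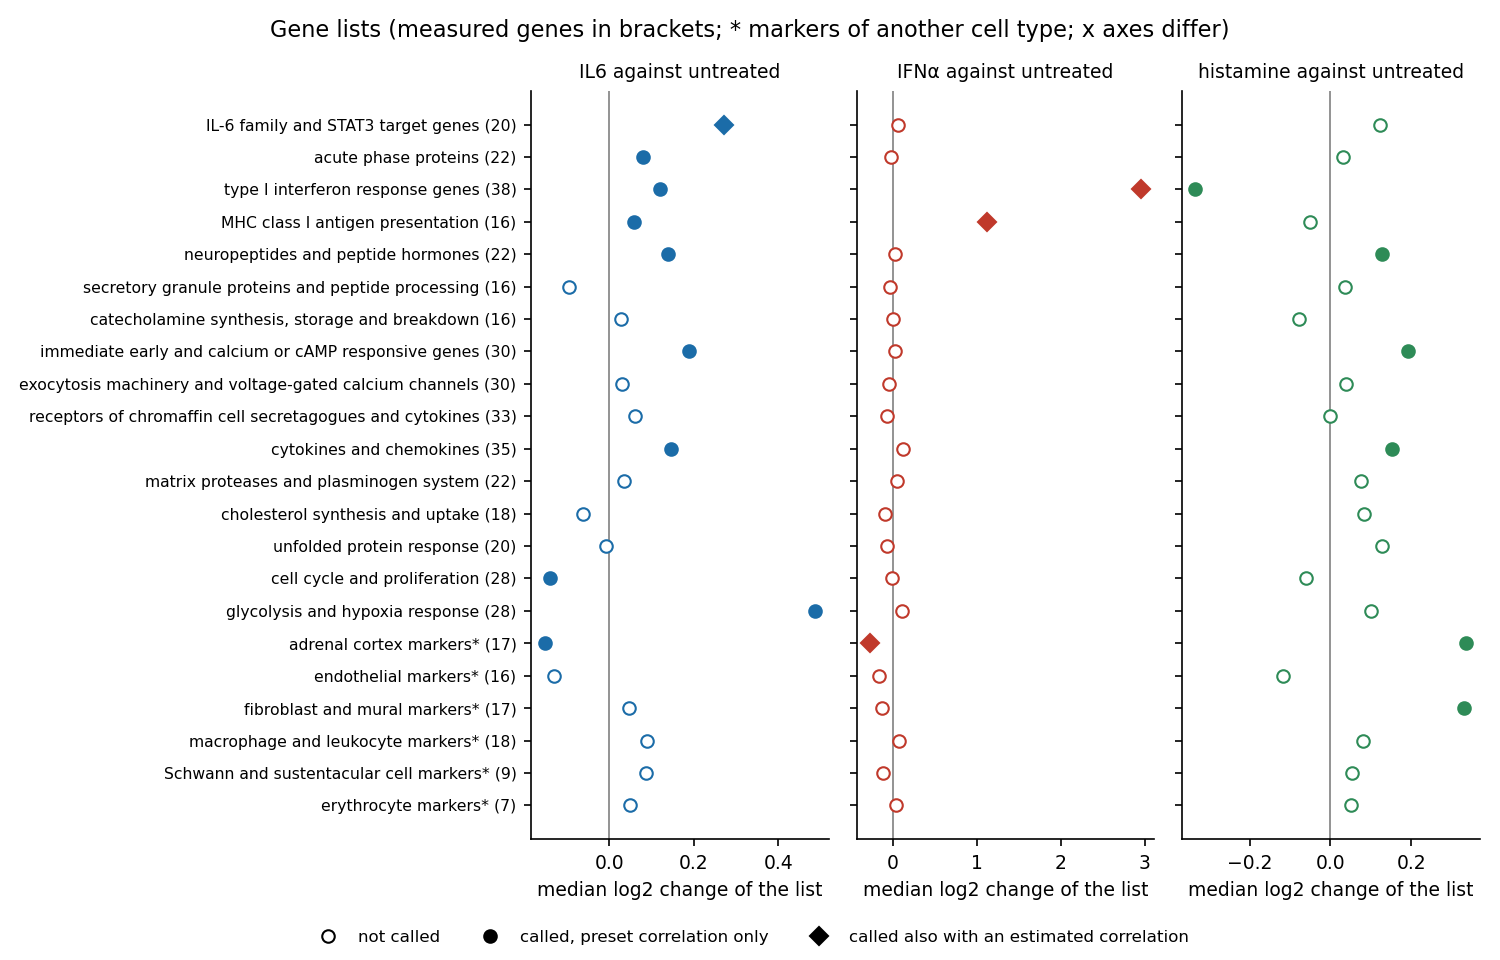
Median log2 change against untreated (x axis, with a separate scale in each panel) of 22 gene lists fixed before the data were examined (y axis, measured genes in brackets). Filled symbols were called by camera and diamonds also with an estimated correlation, which held for the IL6-family and STAT3 targets after IL6 and for the interferon, MHC class I and cortex lists after IFNα.

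The response to both cytokines at 24 h was compared directly, although their doses differed. RSAD2, IFI44, IFI44L, LOC100298356 and ISG15 were lower after IL6 than after IFNα, with log2 differences of -7.07, -6.13, -5.99, -5.64 and -5.39. TNFAIP6 was 15.6-fold higher after IL6 than after IFNα (SE 0.09 on the log2 scale), KCNJ8 at least 8.59-fold, CXCL13 7.94-fold and NTRK2 7.18-fold, and GAP43 was higher by 3.46 on the log2 scale. Limma called 1468 probe sets between the cytokines, 678 higher and 790 lower after IL6.

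A set of 10 genes passed the call in opposite directions. GAP43, TNFAIP6, NTRK2, ATF3, TMOD1, C16H1orf21, CCDC167, the glutamate receptor GRM7 and the adhesion protein NRCAM rose after IL6 and fell after IFNα, and EPHX2, a soluble epoxide hydrolase, fell by 0.71 after IL6 and rose 3.11-fold after IFNα. The second EPHX2 probe set had log2 changes of 0.15 and 0.05, and with the mean of both EPHX2 was not called after IL6 (log2 change -0.28). The tested differences of these 10 genes had sizes between 1.43 and 3.96 on the log2 scale (limma, adjusted p at most 1.98e-08). Selection for opposite calls largely fixed this outcome in advance, so the test adds no separate support. CCDC167 and NRCAM lost the call after IFNα without untreated repeat 2 and IFNα repeat 2, respectively (log2 change -0.58 and -0.57).

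IL6 and IFNα shared 59 called probe sets in the same direction, 29 higher and 30 lower, where independent lists would share 7.53 and 2.69. SCNN1G, an epithelial sodium channel subunit, rose 2.78-fold after IL6 and 3.41-fold after IFNα, GBP1, an interferon-inducible GTPase, 2.65-fold and 9.78-fold, and LMO2 2.32-fold and 2.76-fold. IFI27 and ISG12(B) were the other shared genes of this kind. A further 37 probe sets were called in opposite directions, where independent lists would give 9.04. Across probe sets, which are not independent replicates, fold changes after IL6 and IFNα correlated at r = 0.116. Simulated unchanged groups that shared simulated controls gave r = 0.497, with a covariance of 0.00415 beside the observed 0.00933. They gave at most 1 overlapping call. With no probe set changed in the simulation, this is no reference for the 59 shared calls. The 3 control arrays are too few to split, so part of the excess may come from the shared controls.

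**Figure D3:**
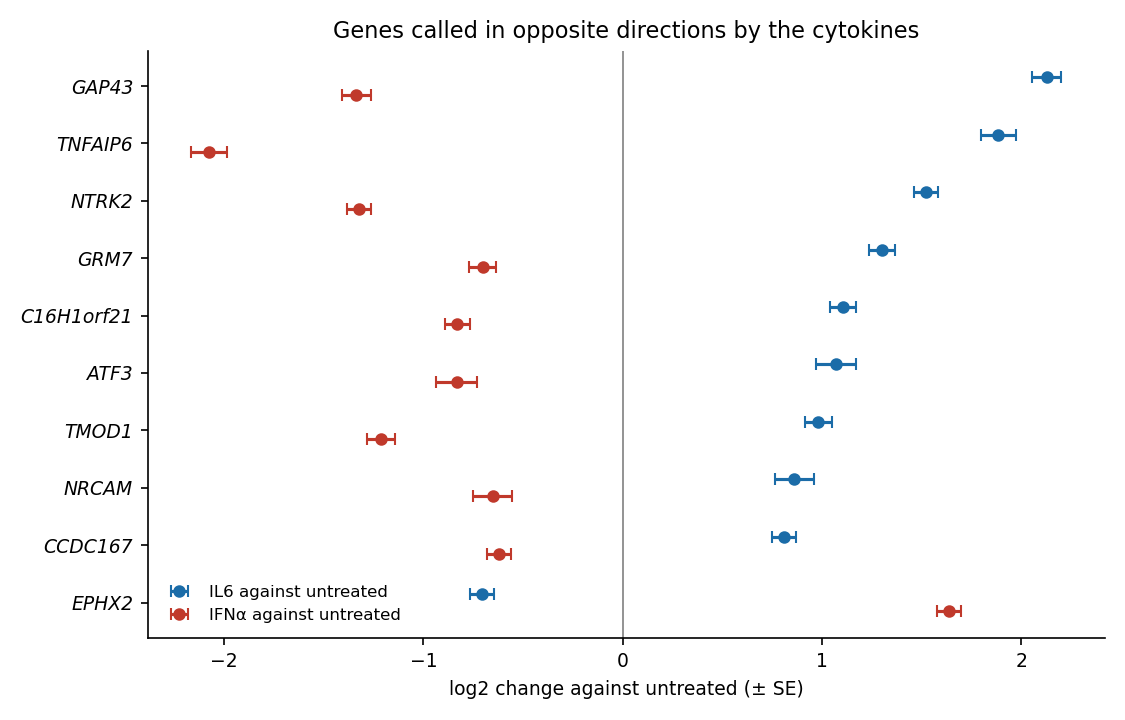
Log2 change against untreated (x axis) of the 10 genes called in opposite directions (y axis), with points for the limma estimates and bars for their SE. GAP43 lay at 2.13 after IL6 and -1.34 after IFNα, and EPHX2 lay at -0.71 and 1.64.

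Histamine, a physiological secretagogue of chromaffin cells, raised several neuropeptide transcripts within 6 h. TAC1, which encodes substance P, rose at least 27.0-fold, from 4.26 ± 0.07 to 9.02 ± 0.12 on the log2 scale (SD, n = 3 each), and VIP, vasoactive intestinal peptide, rose at least 16.5-fold (SE 0.09). The stanniocalcin gene STC1 rose 8.28-fold with a wide error (SE 0.77, or 0.13 without the 3 arrays with raised hypoxia genes), and GAL rose 3.12-fold, from 11.66 ± 0.03 to 13.31 ± 0.03. PNMT rose 4.90-fold, from 8.12 ± 0.09 to 10.41 ± 0.23 (limma, adjusted p = 2.88e-06). In total 8 of 22 neuropeptide and peptide hormone genes rose and none fell (camera, adjusted p = 0.00331; adjusted p = 0.157 with an estimated correlation). PENK, already at 13.89 ± 0.02 in untreated cells, had a log2 change of 0.18 and was not called.

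CREM, a cAMP-responsive regulator, rose 5.83-fold after histamine, the nuclear receptor NR4A1 5.12-fold, FOS 3.99-fold and EGR1 3.95-fold. Of 30 immediate early genes 8 rose and 2 fell, the latter being KLF4 and ATF3, both chosen after their values were seen (camera, adjusted p = 0.00788; adjusted p = 0.179 with an estimated correlation). The other 5 CREM probe sets ranged from -0.12 to 0.70, and the other EGR1 probe set had 0.39. RASD1, a small G protein, SMYD2, a lysine methyltransferase, LOC407218 and the imprinted gene MEST were also among the 10 largest rises, at 5.55-fold, 5.16-fold, 5.92-fold and 4.82-fold. The other 3 MEST probe sets ranged from -0.20 to 1.33. The largest falls among called genes with a symbol were those of OMG, DDO, PYROXD2 and DHRS12. Log2 changes were -1.76 (SE 0.12) for OMG, -1.65 (SE 0.09) for DDO, D-aspartate oxidase, -1.58 for PYROXD2 and -1.57 for DHRS12. MC4R fell by 1.54, CENPT by 1.44, GBP1 by 1.38, ZMYND12 by 1.32, and the serotonin receptor HTR2B and ALG13 by 1.28 each on the log2 scale.

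Of 16 granule and peptide processing genes 4 rose after histamine and none fell: SLC18A2 (1.70-fold), SCG2, which encodes secretogranin II (at least 1.66-fold), PAM, the peptide amidating enzyme (1.64-fold), and PTPRN (1.58-fold). Camera did not call this list (adjusted p = 0.453), and PTPRN had a log2 change of 0.58, below the fold minimum, without untreated repeat 3. Of 16 catecholamine genes PNMT, SLC18A2 and GCH1, which makes the cofactor of tyrosine hydroxylase, rose and GCHFR fell (camera, adjusted p = 0.962; median -0.08, mean 0.10). GCHFR had a log2 change of -0.56, below the fold minimum, without histamine repeat 1. TH, DBH and CHGA were not called, with log2 changes of 0.30, -0.58 and -0.07. Of 30 exocytosis genes NSF rose 1.67-fold and SYT11 fell by 0.60 (camera, adjusted p = 0.83), and SYT11 had -0.58, below the fold minimum, without histamine repeat 2. Among 33 receptors NTRK2 rose 3.10-fold, PTGER3 fell by 0.73 and the nicotinic receptor subunit CHRNB4 fell by 0.67, or by 0.50, below the fold minimum, without histamine repeat 3. The histamine receptor HRH1 had a log2 change of 0.31 and IFNAR1 of -0.09, and neither was called. STAT3, SOCS3 and JUNB had log2 changes of 0.46, 0.01 and 0.48 and were not called, and TIMP1 was the called member of the 20 IL6-family and STAT3 targets (camera, adjusted p = 0.156).

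Interferon-response genes were lower after histamine: 7 of 38 fell and none rose, with a median log2 change of -0.34 (camera, adjusted p = 3.18e-05; adjusted p = 0.179 with an estimated correlation). UBA7 fell by 0.96, DHX58 by 0.81, PARP9 by 0.79 and DTX3L by 0.76. On untreated repeat 1 several of these genes were higher than on the other untreated arrays, and without it the median was -0.22. ISG15 and MX1 had log2 changes of -0.25 and -0.51 and were not called; MX1 passed the call without untreated repeat 3 (log2 change -0.63). TAPBPL was the called member of the 16 MHC class I genes, and fell by 0.63 (camera, adjusted p = 0.393). Of 35 cytokine genes CXCL14, IL18 and TGFB2 rose and CXCL12 fell (camera, adjusted p = 0.0261; adjusted p = 0.334 with an estimated correlation), and the list lost its call without untreated repeat 3 or histamine repeat 1 (adjusted p 0.0593 and 0.0619). Cortex markers, lower after both cytokines, were higher after histamine: CYP11A1 rose 1.91-fold, NR0B1 1.82-fold and HSD3B1 1.77-fold, and none of 17 fell (camera, adjusted p = 0.000816; adjusted p = 0.06 with an estimated correlation). Fibroblast and mural markers were higher as well: MGP, COL1A2 and FN1 rose and none of 17 fell (camera, adjusted p = 0.00331; adjusted p = 0.157 with an estimated correlation). The 3 other MGP probe sets ranged from -0.78 to -0.55, opposite to its brightest one at 0.78. With the mean of all probe sets MGP had a log2 change of -0.27, and COL1A2, FN1 and NR0B1 stayed higher but below the fold minimum (0.53, 0.30 and 0.56).

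Limma called 1369 probe sets after histamine, 717 higher and 652 lower, which represented 345 genes that rose and 294 that fell, and the arrays of both groups were separated in 1367 of them, as in 43.7% of all probe sets, against 10% by chance. No acute phase gene of 22 was called by limma at a fold of 1.5, while 3 had an unadjusted p under 0.05 (camera, adjusted p = 0.61). Counts adjusted over the list alone were the same for every list. Histamine and the cytokines were applied for different times, so their effects are set side by side here and were not tested against each other. IL6 and histamine shared 153 called probe sets in the same direction, 77 higher and 76 lower, where independent lists would share 10.3 and 6.19. KCNE1, a potassium channel subunit, rose 3.89-fold after IL6 and 3.69-fold after histamine, UPP1 2.91-fold and 3.29-fold, and RASD1 2.80-fold and 5.55-fold, with NTRK2 and GAL completing the 5 largest shared genes. Without IL6 repeats 2 and 3 and IFNα repeat 3, UPP1 had a log2 change of 0.90 after IL6, in place of 1.54. Another 32 were called in opposite directions, where independent lists would give 16.2. The covariance of fold changes was 0.0223, against 0.00415 for simulated unchanged groups that shared simulated controls (r = 0.312 and 0.498). The 3 control arrays are too few to split, so part of the excess may come from the shared controls.

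**Figure D4:**
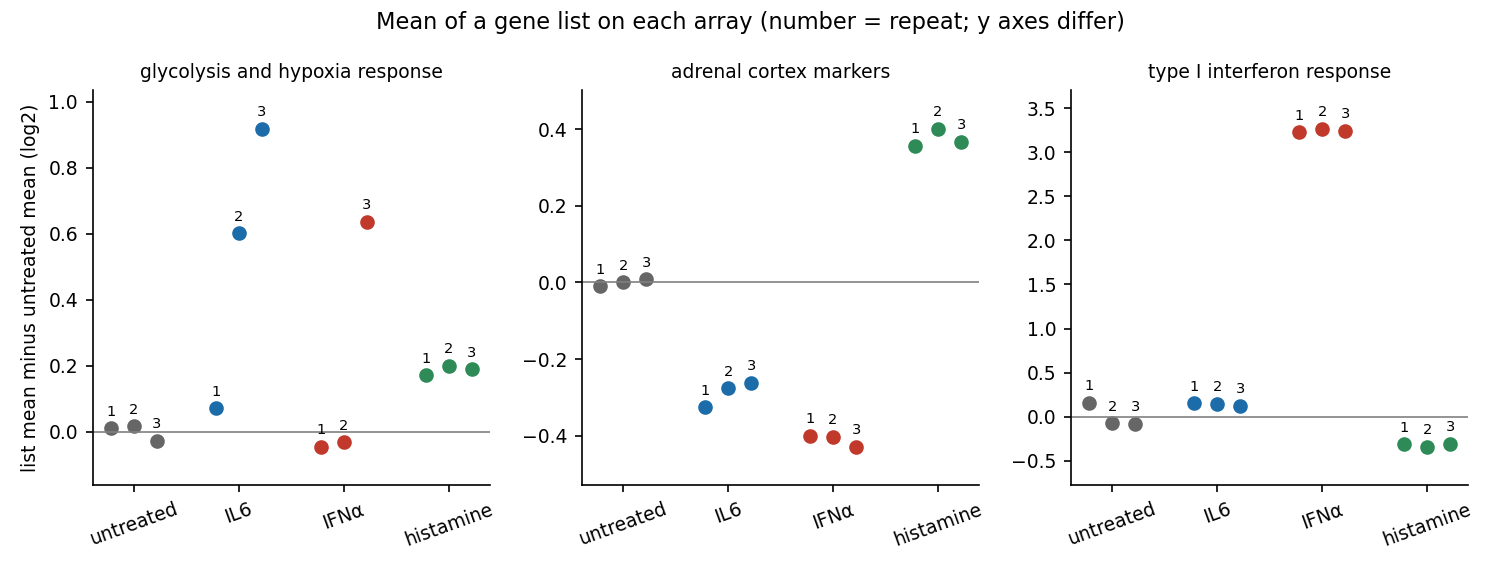
Mean of 3 gene lists on each array minus its mean over untreated arrays (y axis, log2, with a separate scale in each panel), by group (x axis), with the repeat number beside each dot. The glycolysis and hypoxia list stood at 0.60 and 0.92 on IL6 repeats 2 and 3 and at 0.64 on IFNα repeat 3, the cortex list lay between -0.43 and -0.26 on the 6 cytokine arrays, and the interferon list lay between 3.23 and 3.27 on the IFNα arrays.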

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

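The tests on arrays with raised hypoxia genes and on interferon genes after histamine were chosen after those results were seen. The tests on other splits of the arrays were not. For cortex markers the bounds were fixed before the test, but the direction for each treatment was that of the pattern already seen. A total of 10 genes were called in opposite directions by IL6 and IFNα, namely GAP43, TNFAIP6, NTRK2, GRM7, ATF3, TMOD1, C16H1orf21, NRCAM, CCDC167 and EPHX2. Each also had a called difference between the cytokines, an outcome that this selection largely fixed in advance. Outside the tested probe sets, the control probe set AFFX-Bt-AB076373-1_at was higher than untreated after IL6 by 0.67 on the log2 scale. The 3 control probe sets for the translation factor eIF-4E were higher after IFNα by 0.67 (both end sets, 0.673 and 0.667) and 0.71 (middle set).

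Glycolysis and hypoxia genes were raised on IL6 repeats 2 and 3 and on IFNα repeat 3, where VEGFA read 11.17, 11.95 and 11.76 against 9.41 to 9.49 on the other 3 cytokine arrays. RNA degradation is argued against, since 0 of these 3 arrays had a 3′ minus 5′ difference of control transcripts above the other 9. Of the 3, 1 lay outside the range of the other 9 in its hybridisation controls. Within each cytokine group, however, these controls read higher on the raised arrays. After IL6 they read 9.16 and 8.97 against 8.65, and after IFNα 8.98 against 8.73 and 8.77. Untreated repeats 2 and 3 read 9.05 and 8.99, yet their list means relative to untreated were 0.02 and -0.03. A high reading of these controls was therefore not enough to raise the list. A part played by hybridisation within the cytokine groups cannot be excluded. The smaller range of the list mean within a cytokine group was 15.5 times the larger range within the untreated and histamine groups, but the arrays were singled out by this difference, so it restates the pattern and tests no cause. A difference between the culture wells before RNA extraction, such as oxygen or glucose supply, may remain, but the labels give no batch or well with which to test it, and it would mean that the repeats differ by more than array noise. Whether the cytokines contribute in interaction with such a difference is open.

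Cortex markers were lower after both cytokines and higher after histamine, on every array of each group in the list mean. If the share of cortical cells had changed, at least 80% of 12 cortex-restricted markers were predicted to move in the same direction. These markers belong to the list that showed the pattern, so their shares are no separate evidence for it. Under 50% were predicted if it had not, and a move counted where its 95% interval excluded 0. After IL6, IFNα and histamine, 58.3%, 75% and 58.3% did so. Among the 12, SULT2A1, CYP11B1 and MC2R were dim in untreated cells (4.16, 5.20 and 5.29), where a fall shows poorly. The shares after the cytokines may therefore be too low. A changed share and regulation in the cells present cannot be told apart. CYP11A1 and CYP21A2, at similar untreated levels (7.03 and 6.92), differed after IL6 (log2 changes -1.27 and -0.47) but not after IFNα (-1.06 and -1.22, with overlapping 95% intervals), and as they are different probe sets this leaves the question open. Histamine also differed from the cytokines in time, so its opposite direction may reflect 6 h against 24 h of culture.

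Interferon-response genes lay below untreated after histamine with a median of -0.34. Untreated repeat 1 read 7.16 for RSAD2 and 8.78 for ISG15, against at most 4.79 and 7.82 on the other untreated arrays. Without it the median was -0.22 (95% interval -0.39 to -0.08 over genes), with 6 genes lower and 30 of 38 below 0, so the difference did not vanish, but the interval reached beyond -0.1, the bound set for excluding this array as the main source. The median of all probe sets, -0.00167, lies near 0 because the arrays were normalised to each other, so it cannot test a shift by the scaling. A lower basal interferon tone after histamine, or a shorter culture time, may remain as well.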

How the results depend on the processing

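The setting without 3 arrays with raised hypoxia genes was chosen after the data were seen. Among the 26 alternatives for each of the 4 counts of called probe sets, 24 stayed within 1.5 times the count reported, and those that did not changed the fold minimum itself. With no fold minimum the counts were 4170 after IL6 (1604 higher, 2566 lower), 4017 after IFNα, 7581 after histamine and 6839 between the cytokines, with 822 shared by IL6 and IFNα and 1917 by IL6 and histamine; at a minimum of 2-fold they were 149, 322, 253, 549, 12 and 27. Leaving out 1 array gave 564 to 765, 772 to 859, 1364 to 1450 and 1444 to 1615 calls, and 10720 to 12488 probe sets in the F test. Without the dimmer 50% of probe sets, which tests fewer genes, IL6 and IFNα shared 39, and 6 lists were called after IL6 in place of 10 and 5 after IFNα in place of 3. Lists called after IFNα numbered 5 with median centring, 6 with cyclic loess, 5 with the mean of all probe sets, and 3 to 5 when 1 array was left out; the added lists were markers of endothelial, fibroblast or Schwann cells with adjusted p near the threshold, or the cytokine list. After IL6, 5 lists were called without the 3 hypoxia arrays. With an estimated correlation 1 list was called after IL6 and 0 after histamine; fry, which compares no other genes, called 13 after IFNα and 15 after histamine. MGP after histamine reversed to -0.27 (adjusted p = 0.0135) with the mean of its probe sets, whose members disagree; no other called gene named here reversed. NR4A1 after IL6, which was not called, had -0.36 without the 3 hypoxia arrays. The causes of the other moves were not tested. The repeat numbers were not treated as pairs, since not every correlation of deviations between same-numbered arrays was over 0.1 (-0.07 to 0.60), although 9 of 12 arrays correlated best with their own number, a hint of pairing from the data. The replicate block gave 600, 827, 1384 and 1473 calls, and 5 lists after IFNα; it added the call of PNMT after IFNα (log2 change 0.65, adjusted p = 0.0451) and changed no other call of a named gene. Too few splits of 6 arrays exist (10) for a share under 0.05: the real splits, fitted alone, gave 591, 820, 1384 and 1448 calls, and the highest others 0, 0, 0 and 14, with 1 split as large in each, the real one. For the F test 1 of 100 splits, the real one, gave as many as 11783 (highest other 3290). This argues against noise between arrays as the source of that count. As the repeats are called technical, it cannot exclude chance differences between the cultures behind each group. Array number and signal over background limit small changes of dim genes.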

Other observations

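The gene comparisons between IL6 and histamine and the overlap of IFNα with histamine were not planned. The list tests below were fixed before the data were examined. Genes outside the rule for named genes were chosen after their values were seen. Several regulators moved in opposite directions after IL6 and histamine, although the difference between these treatments was not tested and their times differ. The orphan nuclear receptor NR4A2 fell by 0.85 after IL6 and rose by 0.83 after histamine on the log2 scale, and IL18 fell by 0.67 and rose by 0.97. The NR4A2 fall after IL6 rests on its brightest probe set, as the other 3 ranged from -0.09 to 0.06. With the mean of its probe sets NR4A2 was not called after IL6 (log2 change -0.23). The stress-induced factor ATF3 rose by 1.07 after IL6 and fell by 0.73 after histamine, and the prostaglandin receptor PTGER3 rose by 0.69 and fell by 0.73. The interferon-inducible GTPase GBP1 rose after IL6 and IFNα, by 1.41 and 3.29, and fell by 1.38 after histamine. For each of these genes all 3 arrays of either treatment lay on the side stated of all untreated arrays.

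The secreted survival factor MANF rose 2.54-fold after IFNα and 1.75-fold after histamine. After IFNα, SESN2 rose 1.86-fold and the stress sensor EIF2AK3 fell by 0.73 on the log2 scale, with 17 of 20 genes of the unfolded protein response not called (camera, adjusted p = 0.781). After histamine, DNAJC3 rose 1.62-fold and the chaperone HSP90B1 1.58-fold (camera, adjusted p = 0.101), and HSP90B1 had a log2 change of 0.58, below the fold minimum, without untreated repeat 1. After IL6, 0 of the 20 were called by limma at a fold of 1.5, and 8 had an unadjusted p under 0.05 (camera, adjusted p = 0.856). Of 22 matrix protease and plasminogen genes, TIMP1, TIMP3, MMP9 and PLAU rose 1.59-fold, 1.67-fold, 1.65-fold and 1.53-fold after histamine, and camera did not call the list (camera, adjusted p = 0.156). MMP9 and PLAU had log2 changes of 0.58 and 0.57, below the fold minimum, without histamine repeat 3. None of these 22 genes was called after IFNα by limma at a fold of 1.5, and 12 had an unadjusted p under 0.05 (camera, adjusted p = 0.539). IFNα and histamine shared 63 called probe sets in the same direction, and 71 were called in opposite directions, 51 of them higher after IFNα and lower after histamine. Independent lists would share 15.6 higher and 7.68 lower and give 22.7 in opposite directions. The covariance of fold changes was -0.000406, against 0.00416 for simulated unchanged groups that shared simulated controls.

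The remaining lists had few called members. INSIG1 fell after IL6 and FDFT1 after histamine among 18 cholesterol genes, and 0 were called after IFNα by limma at a fold of 1.5, where 6 had an unadjusted p under 0.05 (camera, adjusted p 0.349, 0.747 and 0.762). INSIG1 lost its call when any of 6 arrays was left out (adjusted p up to 0.163). Its log2 change was -0.66, or -0.28 without the 3 arrays with raised hypoxia genes. FDFT1 had a log2 change of -0.40 without histamine repeat 3 and of -0.29 with the mean of its probe sets. In the cell cycle list MCM7 fell by 0.86 after histamine (camera, adjusted p = 0.256), and limma called no member after IFNα, where 7 had an unadjusted p under 0.05 (adjusted p = 0.645). The hypoxia list had 4 risers after histamine (camera, adjusted p = 0.627), PFKFB3, TPI1, P4HA2 and PFKP. PFKFB3, TPI1 and P4HA2 lost the call when 1 of 3, 5 or 3 of the arrays was left out (limma, adjusted p up to 0.0703, 0.0643 and 0.071). Their log2 changes were then at least 0.58, and PFKP lost its call without histamine repeat 3. The fit pools the spread of all groups, and the cytokine arrays varied widely here. TPI1 read 10.70, 10.80 and 10.70 in untreated cells and 11.70, 11.71 and 11.66 after histamine, but 10.83, 11.76 and 12.24 after IL6. Its lost calls therefore need not reflect spread between histamine or untreated arrays. Without the 3 arrays with raised hypoxia genes, 7 of 28 rose after histamine, among them VEGFA, SLC2A1 and EGLN3 with log2 changes of 1.25, 0.74 and 0.62, while PFKFB3 and TPI1 had an adjusted p of 1.53e-07 and 7.45e-10. With the mean of its probe sets PFKFB3 had a log2 change of 0.38 and was not called. Among endothelial markers SELP and TEK fell and CLDN5 rose after histamine (camera, adjusted p = 0.156), and CLDN5 had a log2 change of 0.52, below the fold minimum, without histamine repeat 3. CORO1A was the called leukocyte marker after histamine (1.62-fold; camera, adjusted p = 0.258) and limma called none of 18 after IFNα, where 8 had an unadjusted p under 0.05 (adjusted p = 0.564). Schwann cell markers after IL6, IFNα and histamine had camera adjusted p of 0.349, 0.0677 and 0.747, and erythrocyte markers 0.405, 0.761 and 0.931.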
